A study of Homo sapiens with 22 samples.

How the data were processed

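Bulk RNA sequencing covered 21 libraries of 4 groups, and 1 further m-GC sample was measured by single-cell RNA sequencing, 22 samples in all. Per the labels' protocols, total RNA was made into bulk libraries with the NEBNext Ultra II RNA kit and the single-cell library with the 10x Genomics Chromium 3' v3.1 kit. Whether the bulk counting used strand is not given in the sources used here, so an antisense gene cannot be told from its partner. Per the submitters' processing notes, the tools were STAR, RSEM and Cell Ranger 3.1.0 and the genome build was hg19. The versions of STAR and RSEM are not given in the sources used here. The bulk expected counts per gene, estimates that need not be whole, were deposited by the authors, and the FPKM values per gene were deposited by the authors beside them. The single-cell UMI counts per gene and cell were deposited by the authors as a matrix of 5650 barcodes. The reference annotation at hand is of another build, so no coordinates are given.

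Each bulk table held 57820 genes, and 1 line of the count table, a repeat of header words, named no gene and was left out. For 47 genes the pseudoautosomal Y copy was added to its X copy, and 474 Y-linked genes, XIST and TSIX were left out, leaving 57299. Of these, 39118 identifiers matched the gene name table, 9030 were named from the single-cell feature table and 9151 had no symbol. Expected counts were summed over the technical libraries of an individual and then rounded. The design text calls these replicates technical, so the individual was the unit, n = 2 per group, with 8 sums and 4 residual degrees of freedom. Both giaSC cultures used UC-MSC of 1 person, so their spread does not measure that between stromal donors. Individuals are called culture 1 and culture 2 of their group. The column names of m-GC number the individuals 1 and 2 where the labels use other numbers, so m-GC columns were taken to their group and culture number, not to a labelled individual.

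Depth and effective length were read from the tables. The effective length of a gene in a library follows from its count, its FPKM and the library total, and its median shift against the first pre-GC library was computed in each library. The sums ran from 49.9 to 453.5 M (mega) counts, the smallest in UC-MSC. Technical libraries of 1 individual were compared in 18 pairs. Their chi-square per gene lay between 2.08 and 9.93, so each pair differed by more than sampling noise. The third library of m-GC culture 1 gave the highest values.

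The main test was edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr and the quasi-likelihood F-test with Benjamini-Hochberg adjustment and a threshold of 0.05. All 4 groups shared 1 estimate of the spread (common biological coefficient of variation 0.439), and 26205 genes were tested. CPM values are TMM-scaled. Against a group at 0 counts a fold is a lower bound from a floor of 3 counts over the group, and against 1 to 3 counts it has a 95% counting interval. Intervals and floors cover counting error only.

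Gene lists, 36 of them, were tested with camera of limma 3.58.1 on voom log-CPM at a preset correlation of 0.01, and again with an estimated correlation and with fry, with Benjamini-Hochberg adjustment over all lists and the 3 comparisons. The list test departs from the one first written. On simulated counts in which nothing had been changed, the test over every gene called 3 to 13 of 35 lists between giaSC and UC-MSC in each of 10 simulations, so genes under a mean of 1 CPM in the higher group were left out, after which 0 to 1 of 26 lists were called, and 0 to 3 of 35 between m-GC and pre-GC. With G2 and M phase genes planted at a 2-fold change and that minimum, the preset correlation called the list in 10 of 10 simulations of each comparison. The estimated one called it in 1 of 10 for m-GC against pre-GC, 8 for giaSC against UC-MSC and 7 for giaSC against m-GC. The simulated genes were independent, whereas the correlation estimated for that list in the data was 0.46 in each comparison. The simulations thus do not show how the preset correlation behaves when list members are correlated. The 1 CPM minimum was chosen after the simulation and after the calls without it had been seen, and both counts are given in the closing section. The lists described for each comparison were chosen after the list results were seen. Random lists matched on effective length and mean CPM were first drawn for the cell cycle lists and later added for the other lists called between giaSC and UC-MSC after their results were seen.

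The groups, the tests, the gene lists, the cell type markers, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, per comparison, the 8 genes with the largest positive and the 8 with the largest negative log2 fold change among genes past the threshold, with no overlap of cultures and at least 32 CPM in the higher group. It also took the 2 members with the smallest adjusted p and the 2 with the highest mean CPM of each described list, and always PTPRC, CD34, NT5E, THY1, ENG, CD14, HLA-DRA, POU5F1, NANOG and SOX2. Some genes the rule took are not analysed here, were left out of the named genes and were not replaced, and some named genes were analysed without being described. MMP12, PECAM1 and UHRF1 matched no gene under those symbols and were not analysed here. Genes sharing reads with near-identical copies are uncertain, among them HBA1 and HBA2, DEFA1, SAA1 and SAA2, and TPSAB1 and TPSB2.

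The position of giaSC between m-GC and UC-MSC was computed per culture on linear CPM over genes with an adjusted p under 0.05, a fold of at least 16 between these populations and at least 32 CPM in the higher one. Between the giaSC cultures, ratios were taken after adding 0.5 CPM.

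Single cells were kept with at least 500 genes and at most 20% mitochondrial UMIs, which left 5536. Scrublet in scanpy 1.11.5 marked 1 of them, 0.018%, which for a sample of this size means that it did not work, so doublets remain. Over 100000 UMIs were in 20 cells, the largest 232946. The 5535 analysed cells were clustered on 2000 variable genes, 30 principal components and 15 neighbours with Leiden at resolution 1. A cluster was named from fixed markers of 17 classes, searched among its top 50 genes by fold and otherwise by the markers found in at least 25% of its cells, with at least 3 markers needed. A cluster with a low median UMI count and none of its class markers among its first genes stays unnamed. Genes of a cluster define it and are not findings.

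The tests were tried on simulated counts with 50 genes planted at each of 4 sizes of change. For m-GC against pre-GC (25423 genes), 0% were found at 2-fold, 36% at 4-fold, 70% at 8-fold and 92% at 16-fold, with 9 calls among genes not planted. For giaSC against UC-MSC (25218 genes) the shares were 0%, 34%, 84% and 94%, with 5 such calls, and for giaSC against m-GC (25017 genes) 0%, 34%, 88% and 94%, with 8.

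Alternatives were another scaling (RLE, upper quartile), other filters, DESeq2 1.42.0, a test against a 2-fold change, only the groups compared, 1 library per individual, every library as a sample with and without a replicate block, voom with the individual as a random block, log2(FPKM + 1) and log2(FPKM + 0.1) in limma, haemoglobin and mitochondrial genes left out, and leaving out each culture in turn. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 was used for the rest.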

Results

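Gene expression was measured by bulk RNA sequencing in 4 human cell populations and by single-cell RNA sequencing in 1 further sample. Pre-GC are a pellet of blood cells from which most red cells and lymphocytes had been depleted and which the labels describe as dormant. The mature guide cells, m-GC, were obtained from such pellets after 14 to 18 days in hepatic-conditioned medium. UC-MSC are mesenchymal stromal cells of the umbilical cord, and giaSC are the cells that arise when 10 m-GC per UC-MSC are cultured together. Each population was represented by 2 individuals, with 6 libraries of pre-GC, 6 of m-GC, 5 of giaSC and 4 of UC-MSC. The labels number pre-GC, m-GC and the m-GC used for giaSC as different individuals, so these groups share no blood donor. The giaSC cultures had m-GC donors that also differed from each other, at passage 3 in culture 1 and passage 7 in culture 2. Their UC-MSC came from 1 person, who also gave UC-MSC culture 1. Technical libraries of an individual were summed, so that every mean ± SD below is over n = 2 cultures per group, a blood preparation counting as a culture.

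The UC-MSC libraries stood apart in depth. Library totals were 65.4 to 135.7 M (mega) expected counts in pre-GC, 138.6 to 160.0 M in m-GC, 96.1 to 154.7 M in giaSC and 24.8 to 28.5 M in UC-MSC. The effective gene length depends on the fragment length of a library. Against the first pre-GC library it was shifted by -46.1 to -42.3 bases in UC-MSC, whereas the libraries of the other groups lay between -15.1 and 15.2 bases of it. The UC-MSC libraries thus differed from all others in depth and fragment length, and this difference cannot be separated from the cell type. Haemoglobin transcripts took 0.2585% to 0.6988% of the counts in pre-GC and at most 0.0001% elsewhere. The lowest Pearson correlation of log2 CPM across genes between technical libraries of 1 individual was 0.9954, and between cultures of 1 group it was 0.977, in UC-MSC. Correlations across genes do not treat genes as independent replicates.

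**Figure D1:**
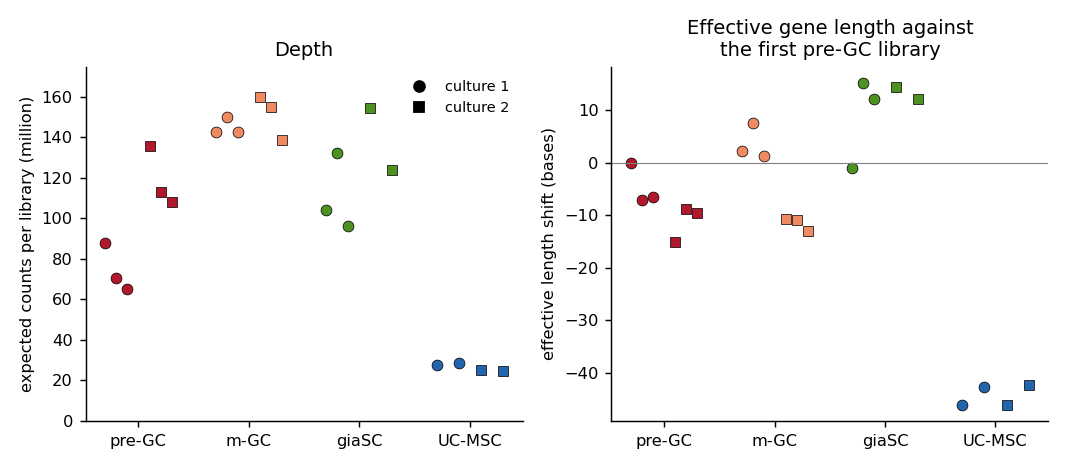
Left, expected counts per library in M; right, shift of the effective gene length in bases against the first pre-GC library. Each point is a library, circles are culture 1 and squares culture 2 of each group; the 4 UC-MSC libraries lie at 24.8 to 28.5 M and at -46.1 to -42.3 bases, apart from the other 17.

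The first comparison set mature guide cells against the blood pellet. The donors of these groups differ and the pellet is a mixture of blood cells. A gene that rose or fell may thus reflect which cells were present, and a change within a cell type was not tested. Macrophage genes of lysosomes and lipid handling rose and blood cell genes fell. GPNMB (ENSG00000136235), a transmembrane glycoprotein of lipid-loaded macrophages, stood at 4049 ± 124 CPM in m-GC and 0.202 ± 0.026 in pre-GC, a log2 fold change of 14.29 (SE 0.81, edgeR adjusted p = 0.00011). MMP9, a gelatinase that degrades extracellular matrix, stood at 17883 ± 3679 against 103 ± 1.79 CPM (7.44, SE 0.85, edgeR adjusted p = 0.00082). In the other direction HBB, the beta chain of haemoglobin, was at 1058 ± 694 CPM in pre-GC, with 3 counts over both m-GC cultures, a ratio of 268861 with a counting interval from 91999 to 1303735 (edgeR adjusted p = 0.0005). The calcium-binding neutrophil protein S100A8 fell from 1291 ± 177 to 15 ± 2.15 CPM (log2 fold change -6.43, SE 0.36, edgeR adjusted p = 0.00017).

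Of 24 measured lysosome and lipid-handling genes, 23 rose and 1 did not pass (camera adjusted p = 1.9e-10, adjusted p = 0.24 with an estimated correlation). The cathepsins CTSB and CTSD, lysosomal proteases, were at 23002 ± 490 and 13045 ± 1345 CPM in m-GC, 124-fold and 36.8-fold above pre-GC. FABP4, a fatty acid carrier, rose from 2 counts over both pre-GC preparations to 170 ± 85.1 CPM. Among 23 monocyte and macrophage identity genes 14 rose and 9 did not pass (camera adjusted p = 0.00047, adjusted p = 0.26 with an estimated correlation). The complement components C1QA and C1QC rose 121-fold and 902-fold and CD68 rose 21.8-fold. LYZ, encoding lysozyme, was at 3636 ± 3688 CPM in m-GC and 1635 ± 913 in pre-GC and did not pass (edgeR adjusted p = 0.28). Of 13 matrix metalloproteinase and inhibitor genes 10 rose and 1 fell (camera adjusted p = 0.0031, adjusted p = 0.23 with an estimated correlation), among them MMP14 at 360-fold and MMP19 at 484-fold. Adjusted over the list alone, 23 lysosome and lipid-handling genes rose, 14 identity genes rose and 1 fell, and 10 metalloproteinase and inhibitor genes rose and 1 fell.

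Inflammatory mediators also moved, with 19 of 26 cytokine and chemokine genes up and 2 down, or 20 and 2 adjusted over the list alone (camera adjusted p = 0.00025, adjusted p = 0.2 with an estimated correlation). The monocyte attractants CCL2 and CCL7 reached 475 ± 274 and 66.4 ± 3.72 CPM, from 0.0691 ± 0.0453 CPM and from 1 count, while CXCL8 was at 610 ± 256 against 453 ± 254 CPM and did not pass (edgeR adjusted p = 0.55). Of 18 immediate early and handling stress genes 11 fell and 3 rose, the same adjusted over the list alone (camera adjusted p = 0.0061, adjusted p = 0.23 with an estimated correlation), and handling of pellet and culture cannot be separated from the populations. Of 18 metallothionein and oxidative stress genes 17 rose, 18 adjusted over the list alone (camera adjusted p = 3.7e-06, adjusted p = 0.26 with an estimated correlation). The ferritin chains FTH1 and FTL were at 25065 ± 281 and 24088 ± 22.6 CPM, 7.27-fold and 10-fold above pre-GC, and SLC7A11, a cystine transporter, was 358-fold above it. Of 20 cholesterol biosynthesis genes 13 rose, 14 adjusted over the list alone (camera adjusted p = 0.0023, adjusted p = 0.44 with an estimated correlation). The call of INSIG1, at 260 ± 24.3 against 35.7 ± 3.64 CPM, was kept in 4 of 8 fits that left out a culture.

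Cell cycle genes were higher in m-GC. Of 24 G2 and M phase genes 23 rose (camera adjusted p = 6.6e-07, adjusted p = 0.33 with an estimated correlation), and of 21 S phase genes 14 rose and 1 fell (camera adjusted p = 0.0054, adjusted p = 0.26 with an estimated correlation). Adjusted over the list alone the counts were the same. The proliferation marker MKI67 went from 3.24 ± 0.643 to 39.6 ± 15.1 CPM and TOP2A, a DNA topoisomerase, from 2.22 ± 0.634 to 21.4 ± 6.04. The member that fell was MCM7, a subunit of the replicative helicase, from 82.6 ± 5.73 to 27.8 ± 0.668 CPM. MCM5 stood at 41.6 ± 4.97 and 40.8 ± 1.28 CPM.

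The blood lineages fell together. Neutrophil genes gave 21 of 24 lower and 1 higher (camera adjusted p = 1.8e-09, adjusted p = 0.14 with an estimated correlation), T cell genes 14 of 18 lower (6.6e-07, and adjusted p = 0.35 with an estimated correlation), cytotoxic lymphocyte genes 14 of 14 (2.5e-06, and adjusted p = 0.26 with an estimated correlation). Lower too were B cell genes 11 of 13 (2.7e-05, and adjusted p = 0.26 with an estimated correlation), platelet genes 14 of 16 (0.00015, and adjusted p = 0.44 with an estimated correlation) and erythroid genes 10 of 13 (0.00044, and adjusted p = 0.2 with an estimated correlation). Adjusted over the list alone, 16 T cell genes fell and the other counts were the same. PI3, an elastase inhibitor, and DEFA1, a neutrophil defensin with near-identical copies, were at 0 counts in m-GC, at least 13194-fold and 18666-fold below pre-GC by a floor of 3 counts over the group. CSF3R, the granulocyte growth factor receptor, fell 64.3-fold. The fall was uneven between m-GC cultures for some lymphocyte genes: PRF1, encoding perforin, was at 2.35 ± 3.26 CPM against 245 ± 104 in pre-GC, a call kept in 5 of 8 fits that left out a culture. Within the platelet list ITGB3, an integrin chain also made by osteoclasts, rose from 13.3 ± 11.5 to 125 ± 57.5 CPM, a call kept in 6 of 8 such fits.

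MHC class II genes, which present antigen, were not called as a list (camera adjusted p = 0.54): 1 of 12 rose, HLA-DMA at 169 ± 16.2 against 69.8 ± 2.7 CPM, a call kept in 4 of 8 fits that left out a culture, and 0 did when adjusted over the list alone. HLA-DRA stood at 1011 ± 261 against 459 ± 205 CPM (edgeR adjusted p = 0.079) and CD74 at 3464 ± 40.8 against 1849 ± 140 (0.34). The leukocyte marker PTPRC stood at 284 ± 37.1 against 1067 ± 328 CPM (edgeR adjusted p = 0.057). CD14, the lipopolysaccharide co-receptor, rose from 189 ± 32.7 to 737 ± 172 CPM and ENG, an endoglin found on macrophages and stromal cells, from 19.6 ± 1.57 to 437 ± 77.8. CD34 fell, at 0.0215 ± 0.0099 against 0.6 ± 0.32 CPM. The pluripotency regulators POU5F1 and NANOG stayed below 1 CPM in every culture, and SOX2, with at most 19 counts in any sum, was too low to be tested.

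Over all genes, 12737 of 26205 tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5792 higher and 6945 lower in m-GC. With upper-quartile scaling 4663 of 13147 calls were higher, since the median log2 fold change of all genes was -0.34 with TMM, -0.41 with RLE and -0.68 with upper-quartile scaling, and changes are relative to it. On log2(FPKM + 0.1) 4020 were higher and 10239 lower. The count was 6069 without the first pre-GC preparation (3461 higher, 2608 lower), 6180 without the second (3593 and 2587), 8540 without m-GC culture 1 (4557 and 3983) and 8201 without m-GC culture 2 (4436 and 3765), so the majority turned to higher genes.

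The second comparison asked how giaSC differ from UC-MSC, of which culture 1 came from the person who gave their stromal cells. Of the 391 genes that rose, 238 stood at least 16-fold higher in m-GC than in UC-MSC with at least 32 CPM in m-GC, and 128 had 0 counts in UC-MSC. CHIT1 (ENSG00000133063), a chitinase of lipid-laden macrophages, was at 94.6 ± 59.7 CPM in giaSC and 0 counts in UC-MSC, at least 2897-fold higher (edgeR adjusted p = 0.0071). CD14 rose from 0.516 ± 0.25 to 15.2 ± 0.118 CPM, a log2 fold change of 4.87 (SE 0.41, edgeR adjusted p = 0.004). THY1, a stromal surface marker, stood at 1195 ± 206 CPM in giaSC and 1171 ± 463 in UC-MSC (log2 fold change 0.03, SE 0.63, edgeR adjusted p = 1). MKI67 (ENSG00000148773), a proliferation marker, fell from 19.5 ± 0.368 to 4.33 ± 0.258 CPM (log2 fold change -2.18, SE 0.32, edgeR adjusted p = 0.021).

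Of 23 monocyte and macrophage identity genes 20 rose, 22 adjusted over the list alone (camera adjusted p = 4.7e-24, adjusted p = 0.14 with an estimated correlation). C1QA reached 10.3 ± 0.145 CPM and C1QC 7.71 ± 4.2, both from 0 counts, at least 315-fold and 236-fold higher. LYZ stood at 150 ± 65.6 CPM with 2 counts over UC-MSC, a ratio of 7052 with a counting interval from 1952 to 58228, and TYROBP, a myeloid signalling adaptor, at 28.1 ± 9.15 CPM with 1 count, a ratio of 2627 from 471 to 103764. CD68 was at 213 ± 97.1 against 30.1 ± 17.6 CPM (edgeR adjusted p = 0.052). Other leukocyte genes at 0 counts in UC-MSC were ITGAX at 56 ± 39.6 CPM, CD52 at 54.4 ± 23.3, TM4SF19 at 52.4 ± 48.2, FGR at 47.5 ± 36.2, CD84 at 40.5 ± 32.1, LILRB4 at 32.5 ± 13.9 and PTPRC at 14.7 ± 13.3. The calls of PTPRC and LYZ were each kept in 6 of 8 fits that left out a culture and that of TM4SF19 in 7. Of 24 lysosome and lipid-handling genes 10 rose, 20 adjusted over the list alone (camera adjusted p = 1.2e-17, adjusted p = 0.2 with an estimated correlation), with APOC1, an apolipoprotein, 259-fold and ACP5, an acid phosphatase, 1808-fold higher. CTSB was at 3116 ± 711 against 1811 ± 530 CPM and did not pass (edgeR adjusted p = 0.43).

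MHC class II genes gave 3 of 12 higher, 7 adjusted over the list alone (camera adjusted p = 5.3e-06, adjusted p = 0.26 with an estimated correlation), at low levels: HLA-DRA was at 11 ± 4.41 CPM against 0 counts, and CD74 at 43 ± 16 against 2.15 ± 2.36 CPM (edgeR adjusted p = 0.065). Complement genes gave 6 of 20 higher, 8 adjusted over the list alone (camera adjusted p = 1.5e-05, adjusted p = 0.2 with an estimated correlation), while the highly expressed members CD59 (655 ± 84.3 against 605 ± 339 CPM) and C3 (480 ± 119 against 167 ± 121) did not pass. Neutrophil genes, several of which macrophages also express, gave 4 of 24 higher, 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0031, adjusted p = 0.34 with an estimated correlation, on the 7 members with at least 1 CPM).

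Of 24 G2 and M phase genes 3 fell over all genes tested and 23 adjusted over the list alone, with a median log2 fold change of -1.72 (camera adjusted p = 6.1e-15, adjusted p = 0.26 with an estimated correlation). CENPF, a kinetochore protein, fell from 14.4 ± 1.25 to 3.78 ± 0.278 CPM. Its call and that of MKI67 were each kept in 2 of 8 fits that left out a culture. S phase genes gave 0 of 21 lower over all genes in edgeR, 11 in DESeq2 and 16 adjusted over the list alone or at an unadjusted p under 0.05, with a median of -1.1 (camera adjusted p = 7.5e-09, adjusted p = 0.2 with an estimated correlation). RRM2, a ribonucleotide reductase subunit, was at 4.7 ± 0.449 against 15.2 ± 0.556 CPM (edgeR adjusted p = 0.078) and PCNA at 38.4 ± 0.647 against 32.9 ± 2.16. The UC-MSC libraries, with 24.8 to 28.5 M counts and the shorter effective lengths, stood apart in the same comparison.

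Among the strongest falls were ESM1, an endothelial proteoglycan, at 0.78 ± 0.45 against 48.9 ± 36.6 CPM, and the interleukins IL1B at 10.2 ± 6.27 against 392 ± 230, IL1A at 4.99 ± 1.89 against 39.8 ± 13.1 and IL11 at 9.72 ± 1.7 against 61.2 ± 27.3. ALDH1A3, an enzyme of retinoic acid synthesis, fell from 476 ± 212 to 28 ± 11.2 CPM and PLAU, the urokinase, from 80.4 ± 4.72 to 7.12 ± 2.11. Of these, PLAU kept its call in 8 of 8 fits that left out a culture, ALDH1A3 in 7, IL1B in 6, ESM1 in 5, and IL1A and IL11 in 3. Cytokine and chemokine genes were not called as a list in this comparison (camera adjusted p = 0.89). Of 26 members 2 rose and 3 fell, or 6 and 3 adjusted over the list alone.

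Few members of the stromal lists passed. Of 16 mesenchymal surface genes 0 passed in edgeR or DESeq2 (camera adjusted p = 0.35; 0 adjusted over the list alone; 1 higher and 2 lower at an unadjusted p under 0.05): NT5E was at 374 ± 263 against 619 ± 63.6 CPM and ENG at 257 ± 78.3 against 305 ± 136. Of 22 matrix genes 1 rose, 2 adjusted over the list alone (camera adjusted p = 0.22). It was DCN (ENSG00000011465), the proteoglycan decorin, at 695 ± 292 against 51 ± 1.78 CPM, a 13.6-fold difference kept in 6 of 8 fits that left out a culture. COL1A1 was at 20855 ± 2208 against 32215 ± 19297 and FN1 at 19763 ± 4809 against 35265 ± 1903. Contractile and TGF-beta responsive genes were lower as a list with 0 of 14 members passing in edgeR or DESeq2 or adjusted over the list alone and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.016, adjusted p = 0.34 with an estimated correlation), for example CNN1 at 57.5 ± 33.3 against 248 ± 30 CPM. Glycolysis and hypoxia genes were also lower, with 0 of 26 passing in edgeR, 2 in DESeq2, 2 adjusted over the list alone and 5 at an unadjusted p under 0.05 (camera adjusted p = 0.014, adjusted p = 0.27 with an estimated correlation). Mitochondrially encoded genes were higher as a list (camera adjusted p = 9.7e-05, adjusted p = 0.35 with an estimated correlation) with 1 of 13 passing, MT-ATP8, also the 1 adjusted over the list alone. MT-ATP8 overlaps another mitochondrial gene and is short, at 277 ± 80.5 against 30.9 ± 21 CPM in libraries that differ in effective length, a call kept in 3 of 8 fits that left out a culture, and MT-CO1 was at 8837 ± 1419 against 8412 ± 1106. The HOX list was lower only with the 1 CPM minimum (camera adjusted p = 0.032, adjusted p = 0.1 over every gene and 0.48 with an estimated correlation), with 0 of 32 genes passing in edgeR, 4 in DESeq2 and 6 at an unadjusted p under 0.05. The same holds for the list of early lineage regulators, on the 5 members with at least 1 CPM (camera adjusted p = 0.027, adjusted p = 0.1 over every gene and 0.26 with an estimated correlation), with 0 of 16 passing in edgeR, 3 lower in DESeq2, and 3 lower and 1 higher at an unadjusted p under 0.05. Adjusted over the list alone, 0 members of either list passed. Log2 fold changes fell with effective gene length across 14082 genes (Spearman rho -0.231), so list medians were set against 10000 random lists matched on effective length and mean CPM. The median was 0.63 for mitochondrially encoded genes against a central 95% of -0.05 to 0.57, -0.5 for contractile genes against -0.3 to 0.27, -0.32 for glycolysis and hypoxia genes against -0.24 to 0.19 and -0.76 for HOX genes against -0.22 to 0.25. Camera had already called these lists against other genes of the same data, so this bears on effective length alone and is no separate evidence of a change. The random lists also ignore the correlation among members, estimated at 0.56 for mitochondrially encoded genes. Only 31.2% of the lineage regulators, 29.2% of the neutrophil genes and 75% of the MHC class II genes had a length here, too few for this comparison.

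Core pluripotency genes were not called (camera adjusted p = 0.051), with 0 of 14 passing in edgeR or adjusted over the list alone, 1 lower in DESeq2 and 1 at an unadjusted p under 0.05. POU5F1, which shares reads with pseudogene copies, was at 0.572 ± 0.575 CPM in giaSC and 0.148 ± 0.177 in UC-MSC, MYC at 69.3 ± 4.86 and 100 ± 7.15 CPM, and SOX2 at 2 counts over both giaSC cultures.

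In all, 440 genes passed edgeR's adjusted p of 0.05, 391 higher and 49 lower in giaSC. Among the 391, 128 had 0 counts in both UC-MSC sums. The balance was less one-sided in other fits, with 1297 higher and 812 lower in DESeq2 and 1036 higher and 1088 lower with voom on every library. DESeq2 called 2109, a fit of these 2 groups alone 125, and fits without UC-MSC culture 1, UC-MSC culture 2 and pre-GC culture 1 called 255, 132 and 277. In simulated counts for this comparison (25218 genes), the test found 0% of genes planted at a 2-fold change, 34% at 4-fold and 84% at 8-fold, so a gene that did not pass cannot be taken as unchanged.

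**Figure D2:**
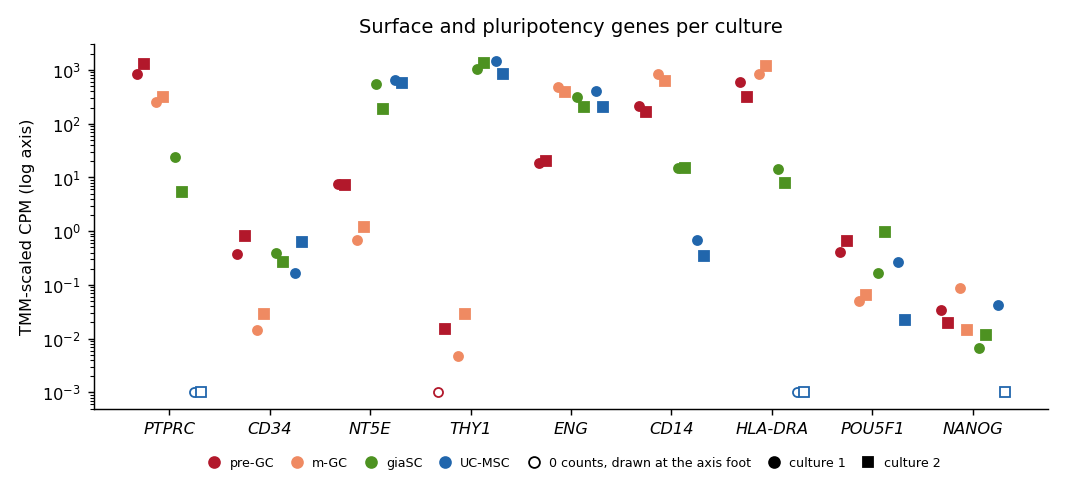
TMM-scaled CPM on a log axis of genes named in advance, one point per culture (circles culture 1, squares culture 2; open symbols mark 0 counts, drawn at the axis foot). THY1 stood at 1195 ± 206 CPM in giaSC and 1171 ± 463 in UC-MSC, and PTPRC at 14.7 ± 13.3 in giaSC between 284 ± 37.1 in m-GC and 0 in UC-MSC.

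The third comparison set giaSC against m-GC, the other cell type of the co-culture, measured here in other donors. Connective tissue genes rose and macrophage genes fell. COL11A1, a fibrillar collagen, was at 665 ± 113 CPM in giaSC and 0 counts in m-GC, at least 184804-fold higher (edgeR adjusted p = 0.0017), and COL1A1 (ENSG00000108821) rose from 0.792 ± 0.911 to 20855 ± 2208 CPM (log2 fold change 14.68, SE 1.62, edgeR adjusted p = 0.00088). CD14 fell from 737 ± 172 to 15.2 ± 0.118 CPM (log2 fold change -5.6, SE 0.41, edgeR adjusted p = 0.00019), and HLA-DRA from 1011 ± 261 to 11 ± 4.41 CPM (-6.52, SE 0.57, edgeR adjusted p = 0.00065).

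Of 22 matrix genes 21 rose (camera adjusted p = 8.7e-10, adjusted p = 0.2 with an estimated correlation), as did 14 of 14 contractile and TGF-beta responsive genes (3.1e-08, and adjusted p = 0.2 with an estimated correlation). LOXL2, a collagen cross-linking enzyme, was 22254-fold higher, and CCN2, a matricellular growth factor, was at 1966 ± 172 CPM with 1 count over m-GC. Of 32 HOX genes, regulators of axial position, 27 rose and 5 did not pass (camera adjusted p = 1e-09, adjusted p = 0.2 with an estimated correlation). HOXC8 was at 109 ± 41.1 CPM against 0 counts and HOXC4 at 14.2 ± 2.84 against 0.0132 ± 0.00492 CPM. Of 16 mesenchymal surface genes 9 rose and 1 fell (camera adjusted p = 0.022, adjusted p = 0.26 with an estimated correlation), with NT5E 400-fold higher, CD248 963-fold, and CD44 at 469 ± 295 against 995 ± 20.5 CPM (edgeR adjusted p = 0.27). Of 29 growth factor genes 18 rose and 4 fell (camera adjusted p = 0.0041, adjusted p = 0.27 with an estimated correlation): BDNF was at 125 ± 10.6 against 0.159 ± 0.104 CPM, whereas CSF1, the macrophage growth factor, fell from 1507 ± 337 to 156 ± 24.6. Adjusted over the list alone, 21 matrix, 14 contractile, 29 HOX, 10 surface and 18 growth factor genes rose, and 1 surface and 5 growth factor genes fell.

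All 23 monocyte and macrophage identity genes fell (camera adjusted p = 2.2e-11, adjusted p = 0.2 with an estimated correlation), as did 22 of 24 lysosome and lipid-handling genes (1.9e-10, and adjusted p = 0.24 with an estimated correlation) and 11 of 12 MHC class II genes (2.1e-05, and adjusted p = 0.26 with an estimated correlation); adjusted over the list alone the counts were 23, 23 and 12. The fall was 42.3-fold for C1QA, 12-fold for CD68 and 7.38-fold for CTSB. CD74 fell 80.6-fold and HLA-DOA 220-fold, the latter from 41.3 ± 5.76 CPM. Of G2 and M phase genes 17 of 24 fell, 20 adjusted over the list alone (camera adjusted p = 3.6e-06, adjusted p = 0.35 with an estimated correlation), and of S phase genes 10 of 21 by both adjustments (8.5e-05, and adjusted p = 0.24 with an estimated correlation). MKI67 was 9.16-fold lower. T cell genes gave 16 of 18 lower, 17 adjusted over the list alone (camera adjusted p = 0.0027, adjusted p = 0.49 with an estimated correlation). Their m-GC level came mainly from culture 2, at a median of 4.332% of pre-GC over 16 T cell genes against 0.243% in culture 1. The mast cell tryptases TPSAB1 and TPSB2, paralogs that share reads, were among the largest falls, at 127 ± 179 and 83.9 ± 119 CPM in m-GC, where they came from 1 culture, and their calls were kept in 3 of 8 fits that left out a culture.

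The test called 9135 genes, 4851 of them higher in giaSC. With RLE size factors 4155 of 9147 calls were higher, a scaling that moved the median log2 fold change of all genes from 0.01 to -0.13. The count was 5117 without giaSC culture 2 and 5126 without m-GC culture 2.

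**Figure D3:**
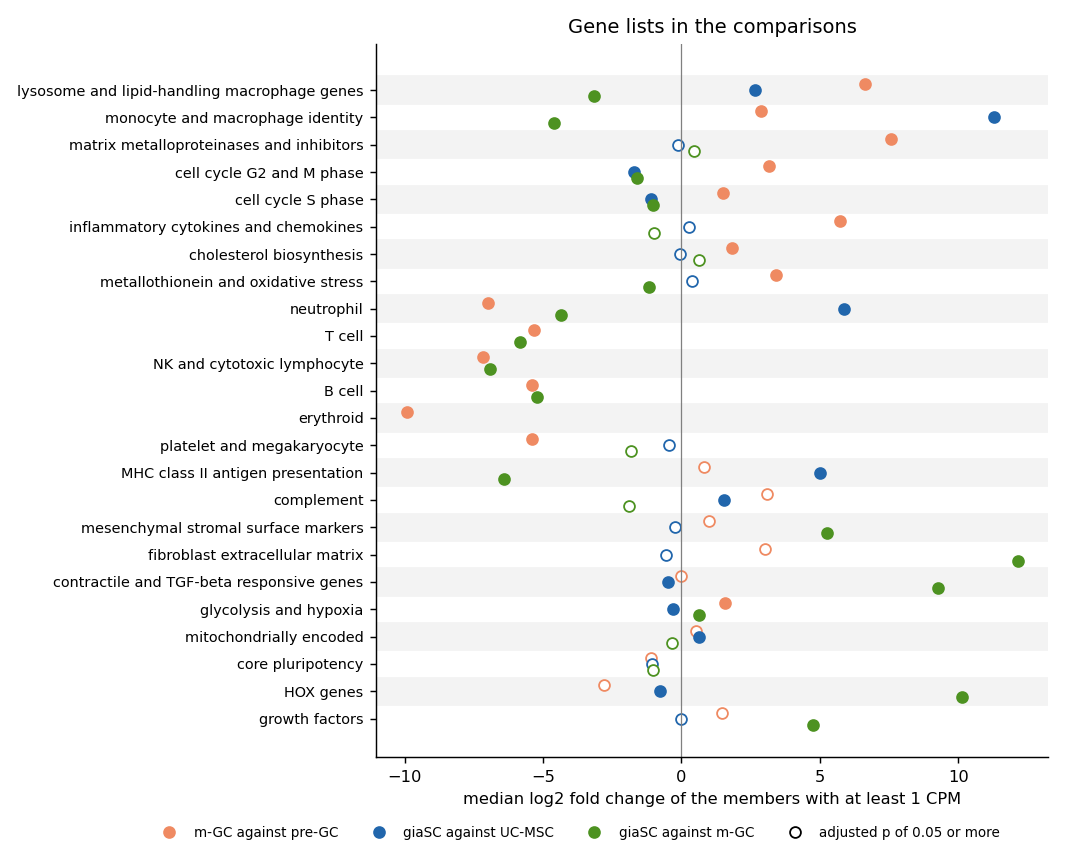
Median log2 fold change of the members of each gene list with a mean of at least 1 CPM in the higher group, one point per comparison; filled points have a camera adjusted p under 0.05 at the preset correlation, and none does with an estimated correlation. Matrix genes stand near 12.16 in giaSC against m-GC and at -0.56 in giaSC against UC-MSC, and G2 and M phase genes at -1.72 against UC-MSC.

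The position of giaSC between m-GC and UC-MSC was read from genes specific to m-GC. The measured m-GC came from other donors than the co-cultured m-GC, and UC-MSC culture 2 from another person than the co-cultured UC-MSC. The shares are thus relative to the measured populations, not to the cells that were co-cultured. Against UC-MSC culture 1 alone the medians over m-GC-specific genes were 7.29% in giaSC culture 1 and 2.67% in culture 2. Over 485 genes with at least 32 CPM in m-GC and at least 16-fold above UC-MSC, the median level of giaSC lay 7.17% of the way from UC-MSC to m-GC in culture 1 (quartiles 4.76% and 9.73%) and 2.51% in culture 2 (1.36% and 3.67%). Over 483 genes specific to UC-MSC the medians were 29.79% and 34.79%, with wide quartiles from -3.56% to 50.51% and from 6.18% to 60.77%. No test was made, and the spread over genes is not an error over cultures.

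**Figure D4:**
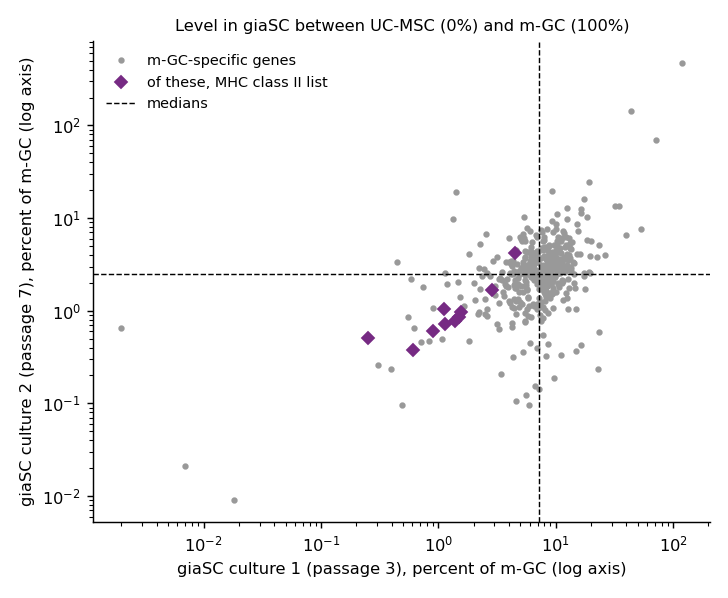
Level in giaSC between UC-MSC (0%) and m-GC (100%), culture 1 against culture 2 on log axes, for the 454 of 485 m-GC-specific genes above 0% in both; dashed lines are the medians over all 485, 7.17% and 2.51%. Diamonds are genes of the MHC class II list, all below both medians except HLA-DMA in culture 2.

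The giaSC cultures differed in donor and in passage, which cannot be told apart, so values are given without a test. Among 5454 genes with at least 32 CPM in 1 of the cultures, 33 were at least 4-fold higher at passage 3 and 18 at passage 7. Of the 33, 20 were m-GC-specific, such as the chemokine CCL22 at 59.73 against 1.5 CPM and CYBB, a subunit of the phagocyte oxidase, at 94.48 against 10.73. At passage 7 the acute-phase genes SAA1 and SAA2, near-identical copies, stood at 321.66 and 261.06 CPM against 20.04 and 19.19, and the nuclear RNA MALAT1 at 6321.02 against 607.47. These genes were chosen after their values were seen.

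The single-cell sample asked which cells an m-GC culture holds. Of 5535 cells, 5489 were macrophage-like, 99.169% with an exact Clopper-Pearson interval from 98.893% to 99.391%, and 46 were T cell-like, 0.831% (0.609% to 1.107%). The macrophage-like cells formed 12 of 13 clusters, each with 12 to 17 of 17 macrophage markers found in at least 25% of its cells. Of them 99.891% held a UMI of CD68, 98.561% of PTPRC, 98.634% of HLA-DRA and 90.199% of CD14. Stray RNA or doublets were visible, since 41.304% of the T cell-like cells held a UMI of APOE and 60.87% of CTSD, and median UMIs were 30713 and 3468 in these classes, so shares are not set against each other. The T cell-like cluster was led by CD2, CD3D, LTB, CD3G and CD3E.

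Among the macrophage-like clusters, 1 of 4.914% (4.36% to 5.517%) was led by the cycling genes MKI67, RRM2 and TOP2A, and this share was 1.771% at a finer clustering resolution of 2. A cluster of 6.49% was led by the dendritic cell marker CCL22 (34.79-fold over other cells), CRABP2 and OCSTAMP, the last a gene of cell fusion. One of 6.72% was led by the interferon-induced genes IFIT1, RSAD2 and IFIT2, and one of 8.02% by the metallothioneins MT1M and MT1H. One of 9.56% was led by the dendritic cell marker CLEC10A, MS4A6A and HLA-DOA, and one of 13.82% included CHIT1 at 6.41-fold. The clusters led by CCL22 and CLEC10A had no other fixed dendritic cell marker among their first 10 genes. Each other marker of that class was found in at most 1.713% of the macrophage-like cells (CCR7). These clusters are thus not shown to be dendritic cells. A cluster of 7.23% had the monocyte markers FCN1 (2.82-fold) and S100A8 (2.38-fold) among its first 10 genes. None of the 17 fixed macrophage markers was among these 10, which also held for most other clusters. Outside the fixed markers, STAB1 (2.37-fold) and MERTK (2.29-fold) were among them. Of the 17, 16 were found in at least 25% of the cells of this cluster. Of the pluripotency genes, SOX2 was found in 0 of 5489 macrophage-like cells, with an exact upper bound of 0.067% on the share of cells with a UMI, which does not bound expression under the detection limit, POU5F1 in 6 and NANOG in 19. In contrast, KLF4 was found in 3433 of these cells (62.543%) and MYC in 2035 (37.074%). CD34 was found in 3 and THY1 in 0. Intervals and floors cover counting error only, and with 1 sample there is no replicate. The summed single cells correlated across 21803 genes with m-GC bulk at a Spearman rho of 0.931 and 0.92 and with the other cultures at 0.723 to 0.802.

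**Figure D5:**
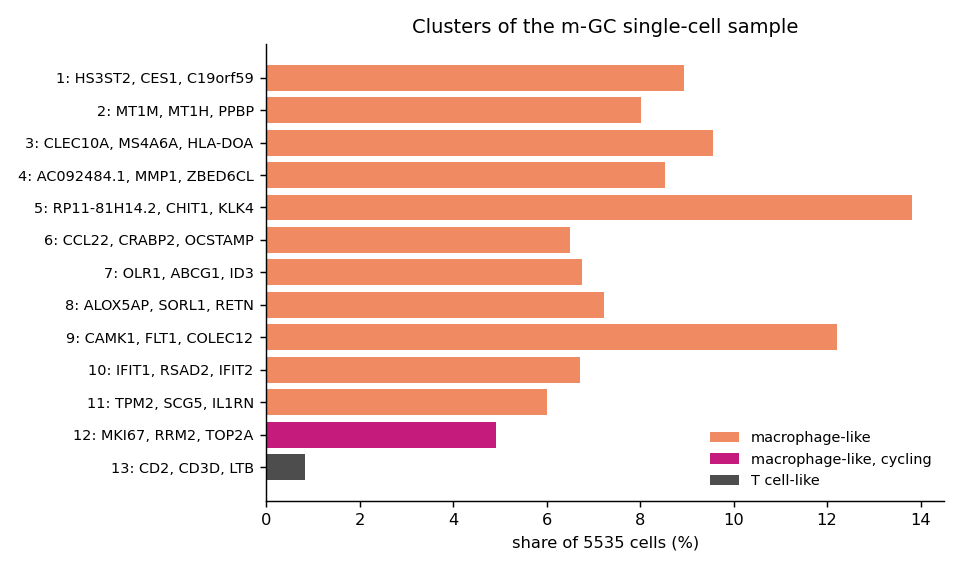
Share of 5535 cells in each of 13 clusters of the m-GC single-cell sample, in percent, named by the first 3 genes by fold. The 12 macrophage-like clusters hold 99.169% of cells, the cycling one among them 4.914%, and the T cell-like cluster 0.831%.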

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

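The fits without the third library of m-GC culture 1, with every sum thinned to the smallest depth, and the 1 CPM minimum of the list test were chosen after seeing the data. The list test over every gene is the one first written, and the other alternatives were fixed before. Where no cause is named, the cause was not tested.

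For m-GC against pre-GC, 12737 genes passed, 8311 with a mean CPM of at least 1, which tests fewer genes, and 7915 against a 2-fold change, a harder hypothesis on the same number of genes. Leaving out 1 culture gave 6069 (pre-GC culture 1) to 13578, with 6180 without pre-GC culture 2 and 8201 without m-GC culture 2. For giaSC against UC-MSC, 440 passed, 2109 in DESeq2 with 5589 adjusted p missing, 249 on log2(FPKM + 1), 887 without a low-count filter, 125 with only these groups, which leaves fewer degrees of freedom, and 2124 with voom on every library. Leaving out 1 culture gave 132 (UC-MSC culture 2) to 423, with 255 without UC-MSC culture 1 and 277 without pre-GC culture 1. The lowest is also the comparison within the UC-MSC donor of both giaSC cultures. For giaSC against m-GC, 9135 passed, 5316 against a 2-fold change and 5117 (giaSC culture 2) to 9692 with 1 culture left out, with 5126 without m-GC culture 2. Without the third library the counts were 12662, 456 and 9117, and thinned 10584, 491 and 7840. A left-out culture leaves a lone one that is assumed to vary like the other groups.

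With every library as a sample, which takes technical libraries for replicates, giaSC against UC-MSC gave 7622 calls without the replicate block and 6849 with it, giaSC against m-GC 16344 and 15866, and m-GC against pre-GC 18804 and 18542. On average the numbers did not pair the libraries: deviations of libraries with the same number correlated at 0.009 (-0.389 to 0.522) and those with another number at -0.004. Yet 12 of 21 libraries correlated best with their own number, and no chance level was computed for this count. Pairing of some libraries by number thus stays open.

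Gene lists called numbered 19, 12 and 20 in the order of the comparisons. With an estimated correlation camera called 0, 0 and 0, with 7, 4 and 7 at an unadjusted p under 0.05, and fry called 27, 12 and 25. Over every gene, the test as first written called 21, 13 and 19, and thinned sums gave 18, 10 and 20. In giaSC against UC-MSC the test over every gene lost the HOX and early lineage lists. It gained haematopoietic stem and progenitor genes as lower (camera adjusted p = 0.026). Senescence and p53 targets (0.041) and metallothionein and oxidative stress genes (0.035) were gained as higher. Leaving out 1 culture gave 18 to 20, 9 to 16 and 16 to 20.

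Over the named genes, no called gene changed direction in any fit. Named called genes lost their call in 32 of their fits for m-GC against pre-GC (6 genes), 81 for giaSC against UC-MSC (18 genes) and 47 for giaSC against m-GC (9 genes). Over all called genes of m-GC against pre-GC, 10499 of 10504 shared calls had the same direction on log2(FPKM + 0.1), 9911 of 9915 on log2(FPKM + 1) and 7291 of 7294 with an FPKM of at least 1. Named genes that had not passed and changed sign follow.

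MCM5 log2 fold change, m-GC against pre-GC (0.03), was -0.08 with 1 library per individual, -0.04 in DESeq2 and with RLE, and -0.05 with every library as a sample with or without the block. It was -0.11 thinned, -0.28 on log2(FPKM + 0.1), -0.27 in both log2(FPKM + 1) fits, -0.31 at a mean CPM of at least 1 and with upper-quartile scaling, -0.07 without a filter, -0.06 with voom, and -0.09 to 0.21 with 1 culture left out. CXCL8 log2 fold change, m-GC against pre-GC (0.43), was -0.21 in the 3 FPKM fits and -0.06 to 1.32 with 1 culture left out. THY1 log2 fold change, m-GC against pre-GC (0.91), was 0.00 thinned and in both log2(FPKM + 1) fits, -0.03 on log2(FPKM + 0.1) and -0.78 to 5.2 with 1 culture left out. With 1 culture left out, LYZ log2 fold change, m-GC against pre-GC, ran from -0.65 to 2.03 and NANOG log2 fold change, m-GC against pre-GC, from -0.88 to 1.69.

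THY1 log2 fold change, giaSC against UC-MSC (0.03), was -0.01 in DESeq2 and with RLE, 0.00 with every library and no block, -0.20 in the 3 FPKM fits and -0.32 to 0.51 with 1 culture left out. CD34 log2 fold change, giaSC against UC-MSC, was 0.02 with 1 library per individual and -0.95 to 0.96 with 1 culture left out. The other ranges with 1 culture left out are these. CD59 log2 fold change, giaSC against UC-MSC, ran from -0.36 to 0.85, ITGB1 log2 fold change, giaSC against UC-MSC, from -0.44 to 0.04, and COL1A1 log2 fold change, giaSC against UC-MSC, from -1.13 to 0.17. PKM log2 fold change, giaSC against UC-MSC, ran from -0.54 to 0.43, and MT-CO1 log2 fold change, giaSC against UC-MSC, from -0.05 to 0.24. KLF4 log2 fold change, giaSC against UC-MSC, ran from -1.73 to 1.53, ENG log2 fold change, giaSC against UC-MSC, from -0.63 to 0.31, and NANOG log2 fold change, giaSC against UC-MSC, from -2.15 to 4.58. IL7R log2 fold change, giaSC against m-GC, ran from -1.07 to 1.06.

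The m-GC share in giaSC lay between 6.98% and 7.65% in culture 1 and between 2.37% and 2.67% in culture 2 over the alternatives. Macrophage-like cells were 99.473% with a higher minimum of genes per cell and 98.534% without a mitochondrial limit, T cell-like cells 0.527% with that minimum, a filter that removes shallow cells, and the cycling cluster 1.771% at resolution 2. The UC-MSC sums hold 49.9 and 56.2 M counts against 278.5 and 332.6 M in giaSC, which leaves only lower bounds for folds against 0 counts in UC-MSC. Thinned to the smallest depth, the comparison gave 491 calls against 440.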

Other observations

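The tests below were chosen after the result was seen, except that of effective length by lists matched on it, which was written before. The genes of this paragraph were chosen after their values were seen. Of the 391 genes higher in giaSC than in UC-MSC, 233 lay within 2-fold of a mixture in both giaSC cultures. In both, 62 lay over 2-fold above it. The mixture was of the measured m-GC and UC-MSC at the median m-GC share, with m-GC of other donors than those co-cultured. That share came from the m-GC-specific genes in the same giaSC cultures. Of the 391, 238 are such genes, so agreement with the mixture was partly built in. For a gene barely expressed in m-GC the mixture lies near the UC-MSC level. The test found 0% of genes planted at a 2-fold change, so such a gene lies above the mixture largely because it was called. Each giaSC culture stood above each m-GC culture for 26 of the 391. Among the 62, PLIN2, which coats lipid droplets, was at 533.08 and 1580.65 CPM in giaSC against means of 67.83 in UC-MSC and 1132.38 in m-GC (edgeR adjusted p = 0.015 against UC-MSC), and ALDH1A1, a retinaldehyde dehydrogenase, at 159.05 and 610.62 against 3.79 and 133.24 (0.01). Others were barely expressed in m-GC: the mechanosensitive channel PIEZO2 stood at 92.31 and 67.56 CPM against 12.55 in UC-MSC (edgeR adjusted p = 0.026), LRATD2 at 137.18 and 218.59 against 24.2 (0.049), DEPTOR, an inhibitor of mTOR, at 46.46 and 50.22 against 10.81 (0.038), and the water channel AQP1 at 17.34 and 80.19 against 0.46 (0.024).

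Macrophage genes stood above UC-MSC in giaSC. Reads leaking from m-GC libraries would carry every m-GC transcript at 1 share, but the MHC class II genes with at least 32 CPM in m-GC stood at a median of at most 0.31 times the share of the m-GC-specific genes. In giaSC cultures 1 and 2 they ran from -0.01 and -0.05 times (HLA-DPB1) to 0.63 and 1.69 times (HLA-DMA). This argues against leakage as the only source, while leakage at a smaller share is not excluded. Too few UC-MSC reads are argued against by the 96.9% of higher calls made again at equal depth. A common share of m-GC cells or RNA in each culture stays open, since 54.4% of the 485 m-GC-specific genes lay within 2-fold of the median share in both cultures, where at least 80% had been set for it and under 50% against it. For the MHC class II genes the median ratio of at most 0.31 lay below the bound set for a common share. It cannot decide, because the co-cultured m-GC came from other donors than the measured m-GC and their MHC class II level was not measured. Remaining m-GC that had lost MHC class II expression, or expression of macrophage genes by the stromal cells, may each contribute and were not tested.

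Cell cycle genes stood below UC-MSC in giaSC. The shorter effective length of the UC-MSC libraries is argued against, since the G2 and M phase median of -1.72 lay at percentile 0 of 10000 random lists matched on effective length and mean CPM, whose central 95% ran from -0.36 to 0.35, for the 23 of 24 members with a length; the S phase median of -1.1 stood against -0.3 to 0.31. The scaling between the groups is argued against by the same percentile of 0, in which a common factor cancels, since it moves the random lists as much. The camera call, which also sets a list against other genes, had shown this before, so the percentile is no separate evidence on scaling. The random lists ignore the correlation among members, estimated at 0.46 for the G2 and M phase list, so the percentile is not a p-value. A separate preparation or culture of the UC-MSC cannot be told apart from the cell type, because all 4 UC-MSC libraries and no other have the shorter effective length. Passage, density at harvest and the co-culture itself may each contribute and were not tested.

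Lymphocyte genes were higher in m-GC culture 2 than in culture 1: the 16 T cell genes with at least 32 CPM in pre-GC stood at a median of 4.332% and 0.243% of their pre-GC level. Leakage from pre-GC libraries is argued against, since the 3 erythroid genes stood at 0.00016 times the T cell share. Lymphocytes left from blood are consistent with the 56.2% of T cell genes, 9 of 16, within 2-fold of their median share, and a T cell-like cluster of 0.831% was seen in the single-cell sample, a separate sample. The protocol removes most lymphocytes by centrifugation, and a difference between donors stays open and was not tested.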
